A study of Mus musculus with 2 samples.

How the data were processed

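MicroRNA-seq libraries from the left cerebral cortex of 2 female mice were analysed, 1 library per animal. Per the labels, total RNA was the starting material and the libraries held RNA below 30 nucleotides. Both libraries were placed in a single group by their source label, and the replicate numbers 1 and 2 were taken from the labels.

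The values deposited by the authors are raw counts of reads per miRNA gene, 1 table per library, with no normalization. The build mm10 and the GENCODE M21 annotation are stated in the metadata deposited with each library. The aligner, its version, the trimming of adapters and any read filter are not given in the sources used here. Each table has 3 count columns: counts without regard to strand, counts on the strand of the read and counts on the opposite strand. The columns carry no header, so their roles were read from the values, and the column with the larger strand-assigned sum in both libraries was used. The text metadata held no measurements and was not used otherwise.

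The first 4 entries of each table are summaries and name no gene. They were left out of all totals. Unmapped reads were 23.4% of reads in animal 1 and 47.1% in animal 2, reads mapping to several places 37.4% and 25.5%, and reads at no listed gene 6.52% and 4.91%. Ambiguous reads numbered 0 on the read strand and 280135 and 149823 in the unstranded column. The number of reads was taken as the sum of the column. Since a separate entry holds reads mapping to several places, and how these reads were treated at genes is not given in the sources used here, counts of miRNAs with near-identical copies are uncertain. All 2202 gene identifiers matched the annotation, from which symbols, positions and overlapping genes were taken.

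CPM was each gene's count over the sum of all gene counts of the library, times 1000000. Log values were log2(CPM + 1). A gene was called detected at 2 CPM or more in both libraries, which is 8.83 counts in animal 1 and 4.56 in animal 2. For each gene the exact Clopper-Pearson 95% interval of animal 1's share of the 2 libraries' counts was compared with the share given by the library totals, and a gene beyond it was called outside counting error. Shares of counts have exact Clopper-Pearson intervals. With 1 group there was no contrast, so no differential test was run and no p-value computed. The common biological coefficient of variation came from edgeR's dispersion estimate with TMM factors and an intercept-only design. Bootstrap intervals used 2000 draws over genes. Each list's median was also ranked among the medians of 10000 random lists of the same size drawn from all measured miRNA genes. The neuron, let-7 and Dlk1-Dio3 medians lay above all of them in both animals, and the vascular median was at the 99.9th percentile in both. The microglia and leukocyte median was at 99.5 in both, and the astrocyte, miR-17, miR-30 and choroid plexus medians were above 99 in both. Those of the oligodendrocyte list were at 97.0 and 96.5, erythroid 96.8 and 96.8, sensory organ 94.4 and 91.9, liver 90.0 and 88.9 and Hox cluster 89.3 and 92.3. The striated muscle, pluripotent cell and X-linked testis medians were 0 and lay above no random list, at percentile 0 in both animals. A median of 0 can only tie with or lie below a random median, and ties were scored as not above. Since 66.1% of measured genes had 0 counts in both animals, percentile 0 does not show that these lists were lower than random lists. The 525 genes with a symbol number under 1000 or a let-7 name held 98.8% of counts on average. The neuron and let-7 lists hold only such genes, and the liver and sensory organ medians also ranked high. A high percentile therefore does not show that a list was particular to the cortex.

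The named genes were set by rule: the 25 with the highest mean CPM, the 10 with the largest absolute log2 ratio between animals at a mean of 100 CPM or more, the 3 most abundant members of each list, and the 5 with the highest opposite-strand count. Any other gene named was chosen after its values were seen. These are Mir92b, Mir124a, Mir137, Mir212, Mir218-1, Mir218-2, Mir449b, Mir449c, the genes named in the closing observations and the genes named as sharing sequence. The lists were neuron, astrocyte, oligodendrocyte, microglia and leukocyte, erythroid, vascular, choroid plexus and ciliated epithelium, Hox cluster, sensory organ, striated muscle, liver, pluripotent cell, let-7, miR-30, miR-17, Dlk1-Dio3 and X-linked testis. Groups, lists, the measures of the main results, the naming rule and most alternatives were chosen before the data were examined; the tests of explanations in the closing observations were chosen afterwards.

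Alternatives were TMM scaling, DESeq2 size factors and dispersions, a filter of 10 CPM or of 1 count in either library, pseudocounts of 0.1 and 5, the unstranded column, leaving out the most abundant gene, leaving out numbered copies, leaving out either library, and thinning the deeper library to the total of the shallower. Hairpin sequences were compared for shared stretches of 22 bases, which 1023 genes (46.5%) had. The counting interval was tested on simulated counts for the 415 detected genes. It put 4.82% of unchanged genes outside and found 78.5%, 90% and 100% of 200 genes simulated at 1.5-fold, 2-fold and 4-fold. A simulated coefficient of variation of 0.4 was estimated as 0.420. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.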

Results

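Small RNA was sequenced from the left cerebral cortex of 2 female B6CASTF1/J mice, 2 months old. The strain name denotes a first-generation hybrid of a C57BL laboratory strain and the wild-derived CAST strain. The assay was microRNA-seq, in which RNA shorter than 30 nucleotides is made into a library so that mature miRNAs, the short RNAs that guide repression of messenger RNAs, can be counted. Both libraries belonged to a single group, so no treatment, age or sex was compared. The questions the design can answer are which miRNA genes the cortex held and how far the 2 animals agreed. The labels number the animals separately, as female 03 and female 04, and call the libraries biological replicates 1 and 2. Both also carry a shared donor identifier. They are called animal 1 and animal 2 here.

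The deposited tables covered 2202 miRNA genes. Animal 1 had 13533476 reads, of which 4415759 (32.6%) were counted at a miRNA gene. Animal 2 had 10143234 reads, of which 2279562 (22.5%) were counted. The unmapped share was 23.4% in animal 1 and 47.1% in animal 2, and of the mapped reads nearly equal shares were counted, 42.6% and 42.5%. Levels are given as CPM, the count scaled to a library total of 1000000. A floor of 3 counts, the most that a count of 0 allows, corresponded to 0.679 CPM in animal 1 and 1.32 CPM in animal 2. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

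Among reads counted at genes, the cortical profile was led by Mir139, the let-7 family, Mir127 and Mir132. Reads in the separate entry for several places were 48.9% of mapped reads in animal 1 and 48.2% in animal 2, more than were counted. The place in this ranking of miRNAs with near-identical copies is therefore uncertain. Mir139 lies in an intron of Pde2a, a phosphodiesterase gene, and alone held 146459 ± 21970 CPM (SD, n = 2), or 14.6% of counts. Mirlet7b followed at 75119 ± 7788 CPM and Mirlet7g at 59117 ± 2115 CPM. Both belong to the let-7 family, which restrains growth and stem cell genes. Mir127, an imprinted miRNA expressed from the maternal chromosome, reached 69263 ± 7474 CPM. Mir132, which neuronal activity induces, averaged 51982 ± 39023 CPM, with a 3.26-fold higher level in animal 2.

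The remaining members of the 10 most abundant miRNA genes were Mirlet7i at 41940 ± 1585 CPM, Mir744 at 39471 ± 965 CPM, Mirlet7d at 35781 ± 1180 CPM, Mirlet7e at 30111 ± 321 CPM and Mir23b at 18200 ± 5348 CPM. These 10 genes held 57.30% of counts in animal 1 (exact Clopper-Pearson 95% interval 57.25 to 57.34%) and 56.19% in animal 2 (56.13 to 56.26%), with a mean of 56.7% ± 0.779 (SD, n = 2). Mir125a, Mir328, Mir99a, Mir652, Mir128-1, Mir330, Mir770, Mir149, Mir433, Mir151, Mir191, Mir29a, Mir30d, Mir23a and Mir126a made up the rest of the 25 most abundant. Their means ran from 17839 ± 1025 CPM for Mir125a to 8195 ± 2167 CPM for Mir126a. In each animal 8 genes made up 50% of counts and 164 made up 99%.

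**Figure D1:**
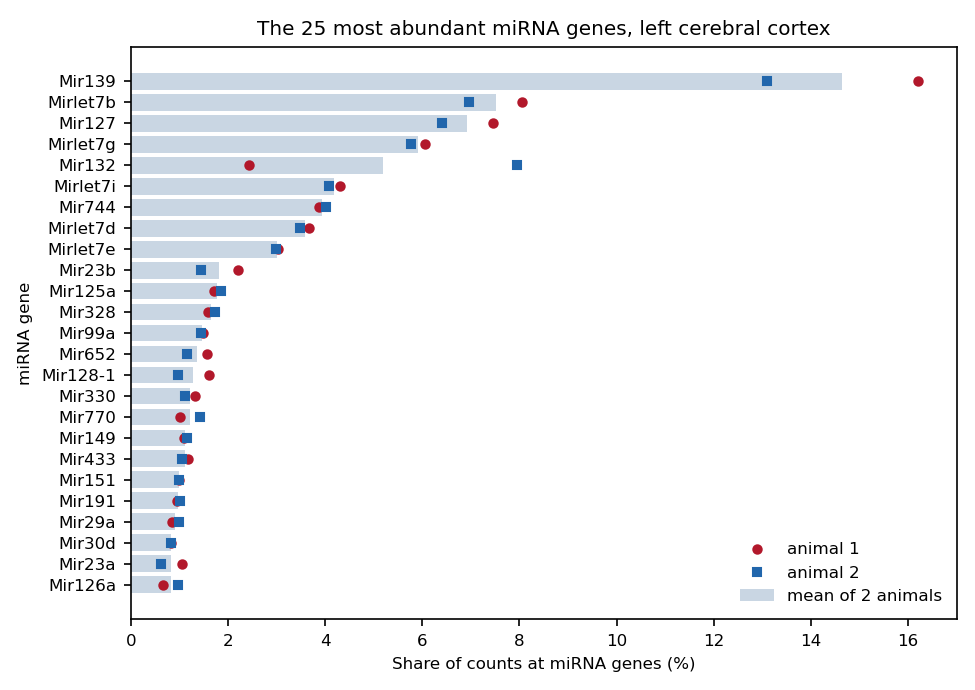
Share of counts at miRNA genes (%, x axis) for the 25 most abundant miRNA genes (y axis), with bars for the mean of 2 animals and points for each animal. Mir139 leads in both animals at 16.2% and 13.1%, and the points of Mir132 lie apart at 2.44% and 7.96%.

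Positions are given on mm10 with the GENCODE M21 annotation. Mir139 (ENSMUSG00000065446.1) lies on chromosome 7 at 101475376 to 101475443, plus strand. Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 at 85707319 to 85707403, in an exon of the noncoding transcript Lncppara. Mir127 (ENSMUSG00000070076.2) lies on chromosome 12 at 109592846 to 109592915, with no annotated host on its strand. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 at 106178840 to 106178927, in an intron of Wdr82. Mir132 (ENSMUSG00000065537.2) lies on chromosome 11 at 75173682 to 75173747, in an intron of the noncoding transcript 1700016P03Rik. Mir744 lies in an intron of Map2k4 and Mirlet7e in an intron of Spaca6. Of the 25 genes, 11 lay in an intron of another annotated gene on their strand, 9 overlapped an exon and 5 had no such gene.

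A minority of the annotated miRNA genes was seen. Counts were 0 in both animals at 1456 genes (66.1%), and 415 genes (18.8%) reached 2 CPM in both. Counting every gene with at least 1 count in either library gave 746 in place of 415.

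The neuron list's median stood far above that of tissues other than brain. The neuron list had 12 of 15 members detected in both animals and none at 0 in both. It was led by Mir132, by Mir128-1 at 12905 ± 4609 CPM and by Mir138-1 at 4677 ± 492 CPM. Mir137 had 3695 ± 909 CPM and Mir212, the neighbour of Mir132, had 1199 ± 409 CPM. The list held 5.93% of counts in animal 1 (exact interval 5.90 to 5.95%) and 10.70% in animal 2 (10.66 to 10.74%). That order rested on Mir132: without it, a choice made after its values were seen, the list held 3.49% in animal 1 and 2.74% in animal 2.

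The 25 off-tissue genes, which join the striated muscle, liver and pluripotent cell lists, had 3 detected members and 14 at 0 in both animals. Of all measured genes, 66.1% were also at 0 in both. Their median was 0 in each animal, against a neuron median of 909 CPM in animal 1 and 1488 CPM in animal 2. With the off-tissue median set at the floor of 3 counts per library, the neuron median was at least 1338-fold higher in animal 1 and at least 1131-fold higher in animal 2. These bounds cover counting error only. They leave out reads mapping to several places, whose treatment at genes is not given in the sources used here. On the log2(CPM + 1) scale the medians lay 10.19 ± 0.50 apart (SD, n = 2), a value that depends on the pseudocount because the lower median is 0. The off-tissue members above 2 CPM in both animals were Mir122, the main liver miRNA, at 48.9 ± 17 CPM, and the muscle miRNAs Mir206 at 19.9 ± 5.18 CPM and Mir499 at 4.15 ± 2.77 CPM. Mir1b had 6 and 4 counts. None of the 14 pluripotent cell genes was detected in both animals; Mir291a had 2 counts in each, Mir290b had 2 and 0, Mir302a had 0 and 1, and 8 members had 0 in both.

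Not every neuron list member was abundant. Mir218-2 had 98.9 ± 49.3 CPM, and Mir218-1 had 48.7 ± 2.52 CPM, level with the off-tissue Mir122. Mir124a, a miRNA largely restricted to neurons, was lowest, as its 3 copies had 11, 6 and 4 counts in animal 1 and 2, 4 and 0 counts in animal 2. Each copy shares a stretch of 22 or more bases with another miRNA hairpin, and the tables hold a separate entry for reads that mapped to several places. The counts of such genes are therefore uncertain as levels. Such genes, 1023 in all, held 4.54% of counts in animal 1 and 4.10% in animal 2. These shares and the ranking of miRNAs cover counted reads only, so they cannot show how many reads of such genes went uncounted. Others among the genes named are Mir128-1, Mir218-1, Mir218-2, Mir138-1, Mirlet7c-2, Mirlet7f-2, Mir107, Mir26a-1, Mir129-2, Mir219a-1, Mir219a-2, Mir92-1, Mir486 and Mir465.

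Glial miRNAs were present at lower shares and were mostly higher in animal 2. The astrocyte list held 0.960% of counts in animal 1 and 1.48% in animal 2, with 8 of 10 members detected. Of these, 6 were higher in animal 2 beyond counting error (5 with TMM scaling) and 1 was higher in animal 1. Mir29a led with 9212 ± 1131 CPM. Mir31 had 171 CPM in animal 1 and 2361 CPM in animal 2, and Mir21a, which rises in reactive astrocytes, had 376 and 1562 CPM. In the oligodendrocyte list, 3 of 5 members were detected and 2 were higher in animal 2. Mir338, an oligodendrocyte differentiation miRNA, had 1001 and 1788 CPM, and Mir219a-2, which acts in the same process, had 634 and 1667 CPM. Mir219a-1 had 7.47 and 6.14 CPM.

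In the immune and vascular lists, the members beyond counting error were all higher in animal 2. The microglia and leukocyte list held 0.180% and 0.234% of counts, with 5 of 6 members detected and 3 higher in animal 2. Mir150, a lymphocyte miRNA, had 1319 and 1668 CPM, Mir146 had 407 and 601 CPM, and Mir142, expressed across blood cells, had 31.7 and 35.1 CPM, inside counting error. The vascular list held 1.15% and 1.52%, with all 3 members higher in animal 2. Mir126a, the endothelial miRNA within Egfl7, had 6662 and 9727 CPM. Mir143 and Mir145a, both smooth muscle miRNAs, had 4590 and 5118 CPM and 216 and 310 CPM.

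Erythroid miRNAs went the other way. Mir451a, an abundant red cell miRNA, had 385 CPM in animal 1 and 43.9 CPM in animal 2, and Mir144 from the same cluster had 40.8 and 9.21 CPM. Mir486 had 33.5 and 38.2 CPM, inside counting error. The list held 0.0459% of counts in animal 1 (exact interval 0.0439 to 0.0479%) and 0.00912% in animal 2 (0.00793 to 0.0105%).

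Lists from neighbouring structures held little. The choroid plexus and ciliated epithelium list held 0.0705% and 0.110% of counts, with 8 of 10 members detected, 3 higher in each animal, and Mir449b and Mir449c at 0 in both. Mir204, expressed in the choroid plexus, had 480 and 652 CPM, and Mir34c, a miRNA of multiciliated cells, had 48.2 and 368 CPM. Mir429, an epithelial miRNA, had 66.8 and 32.9 CPM. The Hox cluster list, which marks hindbrain and spinal cord, had 2 of 6 members detected, Mir10b at 12.6 ± 1.45 CPM and Mir10a at 6.69 ± 0.151 CPM. Mir196b had 5 and 6 counts, and 1 member had 0 in both. The sensory organ list had Mir183 at 19.8 ± 6.91 CPM and Mir182 at 7.74 ± 4.74 CPM, both higher in animal 1, and Mir96 with 1 and 0 counts. No member of the X-linked testis list was detected in both animals; Mir547 had 11 and 1 counts, Mir201 had 6 and 2, Mir465 had 2 and 1, and 11 of 14 members had 0 in both.

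**Figure D2:**
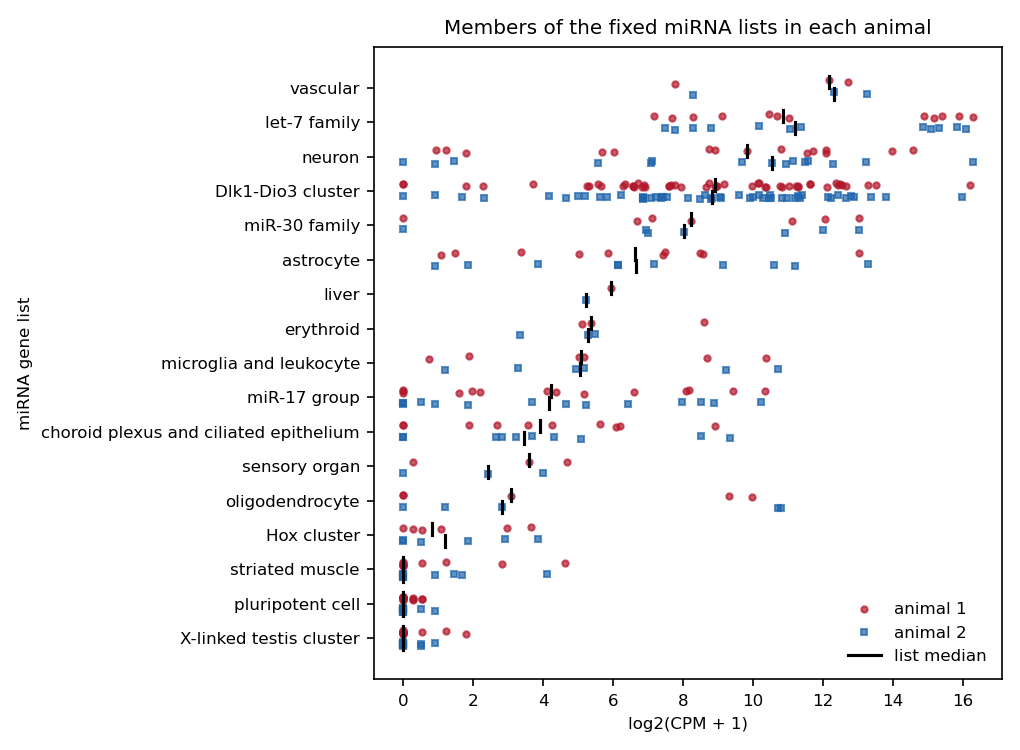
Level of each member of the fixed lists as log2(CPM + 1) (x axis), with circles for animal 1, squares for animal 2 and a black line for each list median in each animal (y axis: list). The neuron medians lie at 9.83 and 10.54, and those of the striated muscle, pluripotent cell and X-linked testis lists at 0.

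Among miRNA families, let-7 took the largest share of those listed. All 12 let-7 members were detected, and together they held 25.8% of counts in animal 1 and 24.0% in animal 2, or 24.9% ± 1.25 (SD, n = 2). These shares cover counted reads only. Among members with a let-7 name, 6 share sequence with another hairpin. Their mean levels had a median of 404 CPM and a maximum of 2109 CPM. The 5 that share none had a median of 41940 CPM and a minimum of 30111 CPM. Mir98, which also shares none, had 2144 CPM. Counts of the sharing members are therefore uncertain as levels, and so is their part of the family share. Of the 12 members, 7 were higher in animal 1, 2 were higher in animal 2 and 3 were inside counting error. The miR-30 family held 1.54% and 1.49%, with 6 of 7 members detected, led by Mir30d at 8369 ± 11.8 CPM, Mir30a at 4176 ± 167 CPM and Mir30e at 2073 ± 195 CPM; 3 members were higher in animal 1 (4 with TMM scaling) and 1 in animal 2. The miR-17 group, a set of growth-promoting miRNAs, held 0.272% and 0.245%, with 9 of 14 listed members detected. Its leading listed members were Mir93 at 1247 ± 70.1 CPM, Mir92-1 at 581 ± 149 CPM and Mir17 at 329 ± 55.3 CPM. Of the listed members, 2 were higher in animal 1, 1 in animal 2 and 6 were inside counting error. The list leaves out Mir92b, which had 8378 CPM in animal 1 and 7745 CPM in animal 2.

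The imprinted Dlk1-Dio3 cluster on chromosome 12 was almost completely detected. Of its 51 listed genes, 49 passed 2 CPM in both animals and 1 had 0 in both. The cluster held 15.99% of counts in animal 1 (exact interval 15.96 to 16.02%) and 15.29% in animal 2 (15.24 to 15.33%), with a mean of 15.6% ± 0.498 (SD, n = 2). Mir127 led, followed by Mir770 in an exon of Meg3 at 12106 ± 2913 CPM and Mir433 at 11158 ± 872 CPM. The cluster did not move as a block, since 19 members were higher in animal 1, 18 were higher in animal 2 and 12 were inside counting error; with TMM scaling these counts were 20 and 16. Log2 ratios of its detected members ran from -1.18 to 1.34. The files do not separate the parental alleles, so imprinting itself was not measured.

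The 2 animals ranked miRNA genes alike but differed in single genes. Each animal had 1 library, so differences between animals and between library preparations cannot be told apart. Across the 415 detected genes, log2(CPM + 1) correlated with a Pearson r of 0.981 (95% bootstrap interval over genes 0.975 to 0.986) and a Spearman rho of 0.975. These are correlations across genes, which are not independent replicates. The median absolute log2 ratio was 0.32, and 276 genes (66.5%) lay within 0.5. The SD of the log2 ratio was 0.71 (0.61 to 0.82), against 0.30 from counting error.

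Among genes with a mean of 100 CPM or more, the 10 farthest apart went in both directions. Mir301, in an intron of Ska2 on chromosome 11 at 87113004 to 87113089, was higher in animal 1 with a log2 ratio of 4.26 (261 against 12.7 CPM). Mir451a was also higher in animal 1, with a log2 ratio of 3.10. Mir31, on chromosome 4 at 88910557 to 88910662, was higher in animal 2 with a log2 ratio of -3.78, followed by Mir34c at -2.90, Mir26a-1 at -2.22, Mir222 at -2.15, Mir21a at -2.05, Mir298 at -2.0, Mir107 at -1.71 and Mir132 at -1.71. Mir132 was the most abundant of these, with 24389 CPM in animal 1 and 79576 CPM in animal 2. Its ratio had a counting interval of -1.72 to -1.70.

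By the exact Clopper-Pearson 95% interval of animal 1's share of the 2 counts, counting error alone puts 5% or fewer genes outside. Of the 415 genes, 235 (56.6%) lay outside counting error. Of these, 112 were higher in animal 1 and 123 in animal 2, and with TMM scaling the order turned to 123 and 116. Only 47 of them also differed by more than 1 in log2, 20 higher in animal 1 and 27 higher in animal 2. The share outside followed the counting SD, which was 0.56 at a mean of 2 to 10 CPM (20.4% of genes outside) and 0.02 at 1000 CPM or more (90% outside). The median absolute log2 ratio was 0.30 and 0.24 in these ranges. This compares 2 libraries and not 2 conditions, so no p-value is given. The common biological coefficient of variation was 0.329 in edgeR, on 1 residual degree of freedom, and 0.123 as the median of DESeq2's gene-wise values. Either value joins differences between animals and between library preparations.

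**Figure D3:**
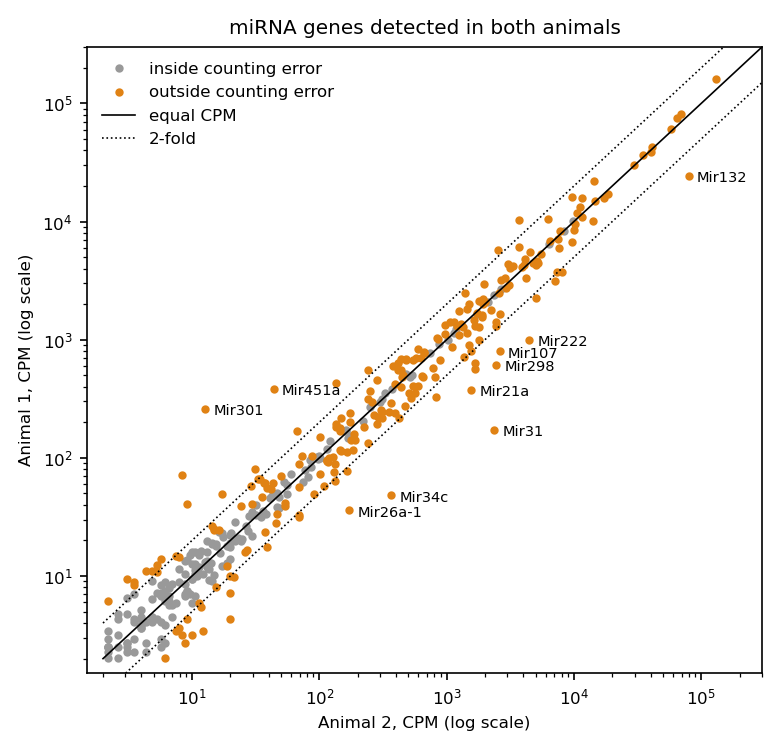
CPM in animal 1 (y axis, log scale) against CPM in animal 2 (x axis, log scale) for the 415 miRNA genes detected in both, with orange points outside counting error and grey points inside. The 10 genes with the largest ratios at a mean of 100 CPM or more are named; the solid line marks equal CPM and the dotted lines a 2-fold difference.

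Strand mattered where miRNA genes overlap on opposite strands. Mirlet7e had 133966 and 68123 counts on its own strand and 0 in both animals in the unstranded column, because Gm25927 lies opposite it. Mir191 had 42073 and 23096 counts and likewise 0 unstranded, with Gm24083 opposite. Mir126a, opposite Mir126b, averaged 0.597 CPM unstranded against 8195 CPM on its strand. Gm25927, Gm24083, Mir126b, Gm25301 and Mir30f had the highest opposite-strand counts, and on their own strand they had at most 2 counts in either animal. Mir451a also has an overlapping gene, Mir451b, and its unstranded counts were 0 in both animals against 1698 and 100 on its strand.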

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

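All tests in this part were chosen after the results they bear on were seen, and the criterion and the families for shared reads at Mir124a were revised after the values were known. With a single group, no biological explanation that the design names was tested.

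Signals lay outside the counts used for the comparisons. Reads mapping to several places made up 48.9% of mapped reads in animal 1 and 48.2% in animal 2, more than were counted at genes in either. Reads at no listed gene made up 6.52% and 4.91% of all reads. On the opposite strand, 212 counts in animal 1 and 90 in animal 2 fell at the 2138 genes with no miRNA gene across from them, led by Mir5620 with 68 and 25 and Mir3083 with 39 and 18. Mir5620 lies on chromosome 7 at 7298891 to 7298946 and had 15 and 28 counts on its own strand. The other 99.9% of opposite-strand counts lay at the 64 genes that overlap a miRNA gene on the other strand.

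Mir124a, the main neuronal miRNA, had 21 counts in animal 1 and 6 in animal 2 over its 3 copies, while Mir132 and Mir137 were abundant. A candidate explanation is that reads shared between identical copies were not counted at any gene. Over 12 families that hold both kinds, members sharing 22 bases with another hairpin differed from members that share none by a median of -3.81 in log2 CPM (95% bootstrap interval -6.27 to 0.84); without hairpins opposite a gene of the same number, as in the Mir129 and Mir219 families, sharing members were lower in 8 of 10 families, with Mir7 higher and Mir669 equal, and the median was -4.70 (-6.42 to -1.99). Families made up of sharing members alone, the kind Mir124a belongs to, were not in that test. Of 29 such families, 13 had a detected member and only 2 had a member at 1000 CPM or more. In these 2, Mir128-1 reached 12905 CPM and Mir138-1 reached 4677 CPM, so sharing did not always go with low counts. In the other families with a detected member, the highest mean ran from 582 CPM for Mir467 to 2.22 CPM for Mir365. The highest mean was 277 CPM in the Mir16 family, 49.0 CPM in Mir24 and 43.5 CPM in Mir9. The explanation therefore stays open for Mir124a, as do truly low levels of the sharing members.

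Log2 ratios of single miRNA genes had an SD of 0.71 between the animals, and 2 animals cannot show whether that is more than animals usually differ. Host transcript level, whether from transcription or cell content, would bring neighbouring miRNA genes together. The 56 pairs within 10 kb, most of them on chromosome 12, were no closer than random pairings. Their median gap lay at percentile 61.15, and at 46.6 when shuffled among their own genes. The Dlk1-Dio3 cluster on chromosome 12 held 15.99% and 15.29% of counts, so neighbours there had little common change to share. The 21 pairs elsewhere lay at percentile 98.4 (89.4 among their own genes) and were no closer either. Single neighbours went both ways, so host level stays open for single pairs. Hairpin GC content had a Spearman rho of 0.04047 with the log2 ratio (-0.05 to 0.14). Pairs with the same miRNA number at separate loci were closer than random pairings (85 pairs, percentile 0.02; without let-7 and numbered copies, 29 pairs, percentile 1.07), as sequence-dependent recovery in the library may produce. Their log2 ratios correlated weakly (r of 0.17), and turnover of mature miRNAs stays open, untested.

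Erythroid miRNAs were higher in animal 1, as blood left in the tissue piece of animal 1 might produce. Mir451a and Mir144 had log2 ratios of 3.10 and 2.03, but Mir486, also a red cell miRNA, had -0.18, so 2 of 3 members passed a ratio of 1. Mir486 shares 22 or more bases with another hairpin and Mir3107 lies opposite it, which keeps its count uncertain. Blood and a difference in these 2 genes alone cannot be told apart here. The leukocyte miRNAs Mir150 and Mir142 were not higher in animal 1.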

How the results depend on the processing

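Of the alternatives to the main values, 43 stayed within a set limit and 14 did not. The limit was the spread between animals for shares and the distance of medians, and 1.5 times for counts. The correlation, the SD of the log2 ratio and the coefficient of variation have no spread between animals, so another limit applied. Settings with a log2 ratio over 1, a mean of 100 CPM or more or a list without a member were added after seeing the data. Those for single genes were also added then. Counting genes with 1 count in either library gave 746, and asking also for a log2 ratio over 1 gave 47, both by their own construction. The median gene-wise DESeq2 coefficient of variation was 0.123; the cause was not tested. The distance between neuron and off-tissue medians became 13.51 and 7.87 with pseudocounts of 0.1 and 5, since the lower median is 0, and 9.38 unstranded, 11.06 without numbered copies and 11.10 without Mir124a. The top 10 share became 59.3% unstranded, 51.4% without Mir139 and 58.9% without numbered copies, and the Dlk1-Dio3 share 16.2%, 18.3% and 16.2%. Without Mir139 the leading gene left both the 10 and the total. In the unstranded column Mirlet7e, 1 of the 10, fell to 0, and the totals fell to 4135839 counts in animal 1 and 2129829 in animal 2. Other effects of that column, and the cause for the copy setting, were not tested. Without either replicate in turn, detected genes ran from 445 to 449, the top 10 share from 56.6 to 57.3%, the distance of medians from 9.83 to 10.54 and the Dlk1-Dio3 share from 15.3 to 16.0%. Without Mir132 the neuron list's log2 ratio between animals reversed, from -0.85 to 0.35, and without Mir31 and Mir21a the astrocyte ratio went from -0.62 to -0.27. TMM scaling shifted every log2 ratio by 0.02 and left 239 genes outside counting error, 123 higher in animal 1 and 116 in animal 2; 228 were shared with the main set. Of the alternatives for single genes and lists, 55 stayed, 16 moved and 1 reversed. Depth limits genes below 10 CPM, where the counting SD was 0.56.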

Other observations

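The pair tests in this part were run after the values were seen, and the genes named were chosen then. Neighbouring miRNA genes on the same strand did not always share a direction. Mir23b was higher in animal 1, with a log2 ratio of 0.61, while Mir27b, beside it on chromosome 13, was higher in animal 2 at -0.96. Mir23a and Mir27a on chromosome 8 repeated this pattern at 0.76 and -0.57. Mir99b was higher in animal 1 at 1.48, while Mir125a and Mirlet7e beside it on chromosome 17 stood at -0.12 and 0.02. Mir296 was higher in animal 1 at 1.19, and Mir298 next to it on chromosome 2 was higher in animal 2 at -2.0. Other neighbours moved together: Mir221 and Mir222 on the X chromosome were at -1.11 and -2.15, Mir132 and Mir212 at -1.71 and -0.71, and Mir451a and Mir144 at 3.10 and 2.03. Mir101a and Mir101b, at separate loci on chromosomes 4 and 19, went opposite ways at 1.33 and -0.72.

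The X chromosome and a repeated imprinted locus were examined as further groups. Of 142 X-linked miRNA genes, 35 were detected, holding 3.67% and 4.06% of counts. That order rested on Mir221 and Mir222, without which the share was 3.20% in animal 1 and 2.81% in animal 2. Mir652 in an intron of Tmem164 led at 13674 ± 2869 CPM, followed by Mir221 at 5880 ± 3062 CPM, Mir676 at 4020 ± 154 CPM and Mir361 at 3592 ± 664 CPM. Within Sfmbt2, an imprinted gene that holds a large miRNA cluster, 7 of 119 genes were detected, with 0.132% and 0.139% of counts. Mir467d had 582 ± 139 CPM and Mir669c had 428 ± 109 CPM. Both share 22 or more bases with another hairpin, so their counts are uncertain as levels. The undetected genes include numbered copies such as Mir467a-1 and Mir467a-2, with 0 counts in both animals, and every Mir467 gene shares such a stretch. The detected number and the share of the cluster therefore cover counted reads only and do not show that its other genes are silent. Of the 470 genes with a symbol number of 5000 or more, 75 were detected, with 0.194% of counts, led by Mir7689 at 524 ± 158 CPM. The 1021 genes with provisional Gm symbols had 10 detected members and 0.0680% of counts.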
